A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

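Yeast cells of 4 strains were grown in rich medium at 30 °C to an optical density of 1.0, per the labels' protocols: a wild-type MOT1 strain, the mot1-14 mutant, and strains living with TBP-Y185C or TBP-F207L in place of Mot1. RNA was extracted with hot acid phenol, poly(A) RNA was prepared from 1 mg, and 500 ng of total RNA was amplified and labelled with Cy3 or Cy5, per the labels. Each mutant was hybridised against WT on 2 yeast oligonucleotide arrays with the dyes exchanged, giving 6 arrays on 3 slides. The mutant was in Cy5 on the first array of each pair and in Cy3 on the second, per the labels. The number of an array within its pair thus stands for the dye orientation and pairs nothing else.

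The deposited scanner files were made with Agilent Feature Extraction 7.5.1 (with the prefix A), per the file headers. They give for each of 10807 spots the mean and local background intensity in each channel, which the authors left without background subtraction or scaling. Processed intensity values, background-subtracted, spatially detrended and dye-normalized, stand beside them, per the file headers. The deposited log ratio is log10 of red over green processed signal, with a p-value of each spot under the scanner software's error model, per the file headers. The authors' series table holds log2 of red over green. This was found by setting it against the scanner values: each probe's value equalled the error-weighted mean of its unmarked spots' log ratios within 2e-04 for 100% of the probes on every array. It is not turned to mutant over WT, although the series' text speaks of mutant over WT, and it is not centred, with column medians of -0.0258, 0.0188, -0.0227, 0.0247, -0.0034 and 0.0203. As deposited, the arrays of a pair correlated at -0.895, -0.951 and -0.883, as exchanged dyes give. Scale, centring and direction of that table are thus known, and it served as an alternative.

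Mean signals were background-corrected by normexp with an offset of 50 and normalized by loess within each array, with limma 3.58.1 in R 4.3.3. The 544 control spots had weight 0 in loess and were left out afterwards. Spots that the scanner software marked as outliers were left out, at most 3.22% of an array's gene spots, and saturated spots were kept. Spots of one probe were averaged, 4007 probes having 2 spots and 2249 having 1. A probe was tested when it was well above background in either channel on at least 2 arrays, which 6232 of 6256 probes met and 24 did not. Each gene had 1 probe. Probes carry the array's systematic names, of which 5756 matched the reference table of assembly R64 and 500 did not. The table served only for current symbols, 1290 of which replaced older ones, and for the order of genes along chromosomes. Near-identical paralogs, such as those of ribosomal protein, hexose transporter, acid phosphatase, IMD, COS and PAU genes, may share signal, and their values are uncertain.

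One limma model over all 6 arrays held a coefficient for each mutant, signed by dye orientation, and an intercept for the dye effect of each probe. It left 2 residual degrees of freedom, to which the empirical Bayes prior added 4.68. Log2 ratios were tested against 0 for each mutant, and differences of coefficients for each pair of mutants, with Benjamini-Hochberg adjustment at 0.05 over all genes tested. Adjusted p-values of single genes are from this model throughout. WT served as 1 control sample, so its own spread is not in the test. A probe not well above background in a strain's channel on both arrays has only a bound there, given as at least N-fold, against the lowest signal among probes well above background. In the mot1-14, TBP-Y185C and TBP-F207L comparisons, 40, 69 and 5 genes had only such a bound for WT.

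A gene changed in mot1-14 was called restored in a bypass strain when that strain differed from mot1-14 in the direction of WT, did not pass against WT, and kept under 50% of the log2 change. It was partly restored when the difference passed but the strain still passed in the same direction, retained when it passed in the same direction without such a difference, opposite when it passed in the other direction, and otherwise unresolved. Because genes picked for a large change regress to the mean, the share left was also taken with genes picked on 1 mot1-14 array and measured on the other. Of 42 gene lists, 41 were tested with limma's camera at its preset correlation, adjusted over the lists, with an estimated correlation and fry beside it. Named genes followed a rule: the 10 largest rises and falls of each mutant among genes that passed, with the same sign on both arrays and a measured signal in the brighter strain. To these came MOT1, SPT15, INO1, HSP26, BNA1 and URA1, up to 4 members of each described list, the 5 largest in each direction of each direct comparison and the 5 largest of each class. The design, lists, named-gene rule and alternatives were fixed before the data were examined, except where a part says otherwise. Other genes named, such as PEA2 for its place beside SPT15, were chosen after their values were seen.

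The tests were checked on simulated data built on the spread of 6126 genes in the mot1-14 comparison. Of 50 genes changed by 0.25 on the log2 scale 42 were called with the right sign (84.0%), and all 50 at 0.5, at 1 and at 2. Of 5886 unchanged genes 11 were called (0.187%). This simulation held only the spread between arrays, so false calls from variation between RNA extracts are left out of that share. For TBP-Y185C against mot1-14, 78 of 78 restored genes and 70 of 72 retained genes (97.2%) with simulated changes of 0.5 or more received the right class. So did 100 of 100 newly changed genes with changes of 1. Classes of smaller changes were not scored. In the data the median size of called changes in mot1-14 was 0.33, and 5 of 621 newly misregulated genes in TBP-Y185C reached 2-fold. Camera at its preset correlation called 1 list shifted by 0.15 and 0 of 40 others. The simulated genes varied independently, so this does not test the preset correlation for lists whose members vary together. In the data the estimated correlation was 0.51 for general stress genes and 0.087 for ribosome biogenesis genes. With an estimated correlation it missed the shifted list, also with the shift raised to 0.25, 0.5, 1 and 2. Chance overlaps between mutants came from 20 simulated sets of 3 mutants without any effect, with 1 WT extract common to all arrays, an extract of each mutant and the noise of the arrays. The SD between extracts, 0.15, was set from the difference of the bypass strains, which holds real differences too. With that variation and no effect, TBP-Y185C had on average 1858 retained, 857 restored and 917 newly misregulated genes.

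Alternatives covered no background correction, the deposited log ratios, median centring, the series table, both filters on dim probes, no dye term, each mutant's arrays alone, outlier spots kept, a 2-fold threshold, the deposited p-values of single spots at 0.01 on both arrays, and each array left out. Averaging several probes of a gene was void, since no gene had more than 1. Slide as a block was not run, since each slide held 1 mutant. The test of TATA motifs in promoters was not run, since no genome sequence was used here.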

Results

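Gene expression in budding yeast was measured on 6 two-colour oligonucleotide arrays. Mot1 is an ATPase that removes the TATA-binding protein (TBP) from DNA, and the study compared a mot1 mutant with strains in which a TBP variant lets cells live without Mot1. The mutants were mot1-14 and the bypass strains, which carried TBP-Y185C or TBP-F207L. Per the labels, each mutant was the same parent strain with a plasmid for its allele. RNA from each of these 3 mutants was hybridised on 2 arrays against RNA of the wild-type MOT1 strain (WT), with the dyes exchanged between the arrays of a pair. Each array held 10807 spots for 6256 gene probes, and 6232 probes entered the tests. The median red signal was 8.05 to 22.7 times the local background on the 6 arrays and the median green signal 6.74 to 10.8 times. After both arrays of a pair were turned to mutant over WT, their log2 ratios correlated across genes at r = 0.93 for mot1-14, 0.96 for TBP-Y185C and 0.94 for TBP-F207L. The labels do not say whether the arrays of a pair came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. WT was the reference on every array, so its own spread is left out of each test, and the number of arrays, 2 per mutant, limits the precision.

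The genes that define the strains were examined first. MOT1 (YPL082C) transcript was 4.51-fold higher than WT in mot1-14 (log2 2.17, SE 0.30, adjusted p = 0.000518) and lower in both bypass strains, with log2 changes of -3.51 in TBP-Y185C (SE 0.30, adjusted p = 3.44e-05) and -2.58 in TBP-F207L (SE 0.30, adjusted p = 0.000185). With the deposited log ratios the MOT1 values of the bypass strains were -4.98 and -3.62. On single arrays the MOT1 log2 ratio was 2.24 and 2.11 in mot1-14, -3.73 and -3.28 in TBP-Y185C, and -1.74 and -3.41 in TBP-F207L. SPT15 (YER148W), which encodes TBP, rose 16.8-fold in TBP-Y185C (log2 4.07, SE 0.10, adjusted p = 2.39e-07) and 12.4-fold in TBP-F207L (log2 3.63, SE 0.10, adjusted p = 3.34e-07). In mot1-14, SPT15 was at -0.36 (SE 0.10, adjusted p = 0.0129), and without the first mot1-14 array at -0.12, which no longer passed the test. PEA2, the neighbour of SPT15 on the chromosome and a polarity protein, rose by 3.54 in TBP-Y185C and 3.23 in TBP-F207L and was at -0.32 in mot1-14. Among the marker genes commonly used on yeast plasmids, TRP1 rose by 4.83 in TBP-Y185C and 4.51 in TBP-F207L and was at -0.59 in mot1-14. LEU2, an enzyme of leucine synthesis and also a marker, rose in all 3 mutants, by 3.02 in mot1-14, 1.95 in TBP-Y185C and 1.89 in TBP-F207L. URA3 was at -0.07 in mot1-14 (adjusted p = 0.245), -0.28 in TBP-Y185C and -0.25 in TBP-F207L. Since the alleles were on plasmids, values of MOT1, SPT15, its neighbour PEA2 and the marker genes may reflect the strain construction. This holds here and in the comparisons below, and regulation of these genes cannot be told apart from it.

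**Figure D1:**
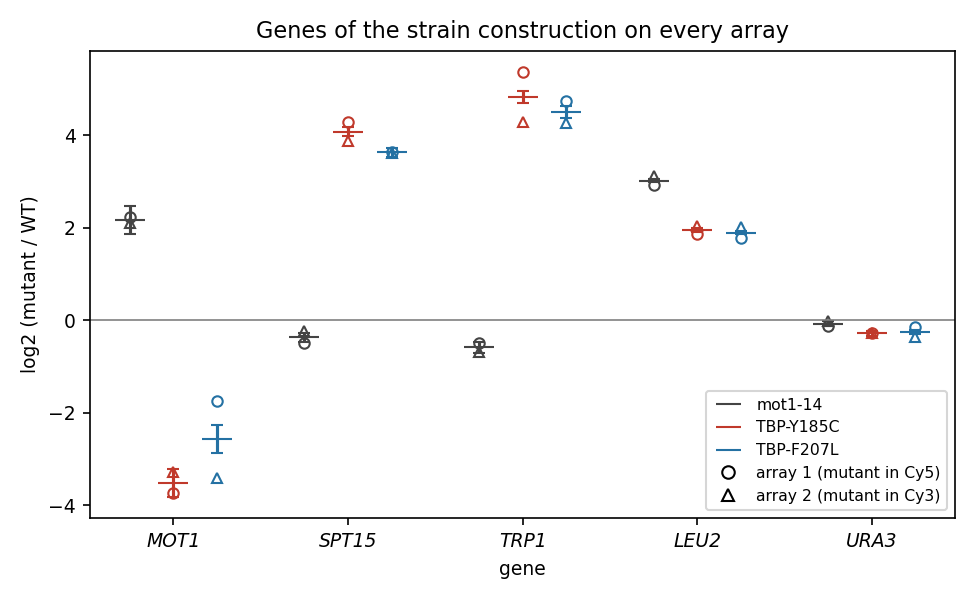
Log2 ratio of mutant over WT for MOT1, SPT15 and marker genes in the 3 mutants. Circles are arrays with the mutant in Cy5, triangles arrays with it in Cy3, and bars the fitted value with its standard error. MOT1 lies above 0 in mot1-14 and below 0 in both bypass strains, where its value on array 1 of TBP-F207L (-1.74) stands above that on array 2 (-3.41), and SPT15 lies between 3.62 and 4.28 on the 4 bypass arrays.

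The comparison of mot1-14 with WT asked which transcripts depend on Mot1. TMA10, which encodes a ribosome-associated protein, rose 15.2-fold in mot1-14 (log2 3.93, SE 0.11, adjusted p = 4.72e-07). The small heat shock gene HSP42 rose by 2.66 on the log2 scale (SE 0.09), CYC7, an isoform of cytochrome c, by 2.65 (SE 0.13), and the glycogen phosphorylase gene GPH1 by 2.45 (SE 0.04). The largest falls were in FDC1, a ferulic acid decarboxylase, at -1.77 (SE 0.04), and BNA1, an enzyme of NAD synthesis from tryptophan, at -1.77 (SE 0.04, adjusted p = 3.35e-07).

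In total 4465 of 6127 genes passed the test in mot1-14 (72.9%), of which 2323 rose and 2142 fell. Loess centres each array near 0, so a shift of all transcripts together could not be seen. The near-even splits of this and the other comparisons depend on that centring. With the deposited log ratios 2094 rose and 2261 fell in mot1-14, 2364 and 2551 in TBP-Y185C, and 2360 and 2439 in TBP-F207L. The deposited p-values on both arrays called 1512 genes in mot1-14, and 2066 and 1399 in TBP-Y185C and TBP-F207L. Variation between RNA extracts may be missing from these tests. With such variation, simulated mutants without any effect had on average 1858 genes that passed in mot1-14 and were retained in TBP-Y185C. Most changes were small, with a median size of 0.33 on the log2 scale among these genes. Only 312 changed by 2-fold or more, and 276 of the 312 rose (88.5%). After TMA10 and LEU2, the largest rises were GPG1 at 2.70, HSP42, CYC7, GPM2 at 2.47, AIM19 at 2.47, HSP30 at 2.46, GPH1 and HSP12 at 2.45. GPM2 is a homolog of phosphoglycerate mutase, and HSP30 and HSP12 encode membrane-associated stress proteins. After FDC1 and BNA1, the largest falls were HO, the endonuclease of mating-type switching, at -1.62, TMA20 at -1.53, the DEAD-box helicase gene DBP2 at -1.51, the seryl-tRNA synthetase gene SES1 at -1.43 and the glutathione transferase gene GTT2 at -1.43. ARX1, an export factor of the large ribosomal subunit, followed at -1.35, the cap-binding gene STO1 at -1.23 and the RNA-binding protein gene SCP160 at -1.18. Each of these genes moved the same way on both mot1-14 arrays. INO1, the first enzyme of inositol synthesis, rose by 1.21 (SE 0.05, adjusted p = 1.33e-06), the small heat shock gene HSP26 by 1.69 (SE 0.06, adjusted p = 1.06e-06), and URA1, of pyrimidine synthesis, was at -1.02 (SE 0.04, adjusted p = 1.19e-06).

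Among gene lists fixed before the data were examined, 18 of 41 differed from the other genes in mot1-14, 12 upward and 6 downward. Of 91 ribosome biogenesis genes, 89 fell, none rose and 2 did not pass (median -0.67, adjusted p = 1.18e-20, or adjusted p = 0.556 with an estimated correlation). PWP2 at -1.09 and UTP21 at -1.07, both parts of the small-subunit processome, followed DBP2 and ARX1. Of 34 translation factors, 26 fell and 2 rose (median -0.37, adjusted p = 3.35e-06, or adjusted p = 0.556 with an estimated correlation), among them the poly(A)-binding protein gene PAB1 at -0.99. Of 139 genes for cytoplasmic ribosomal proteins, 69 fell, 35 rose and 35 did not pass (median -0.12, adjusted p = 0.0306, or adjusted p = 0.593 with an estimated correlation). Of 43 general stress genes, 41 rose and none fell, 27 of them by 2-fold or more (median 1.25, adjusted p = 3.71e-13, or adjusted p = 0.556 with an estimated correlation). The glutamate decarboxylase gene GAD1 rose by 2.40. Of 43 respiratory chain genes, 40 rose and 2 fell (median 0.52, adjusted p = 1.26e-08, or adjusted p = 0.556 with an estimated correlation). The succinate dehydrogenase genes SDH2 and SDH4 rose by 1.75 and 1.52, and COX5B, a subunit of cytochrome c oxidase, by 1.64. Of 21 trehalose and glycogen genes, 20 rose and 1 fell (median 0.81, adjusted p = 6.15e-07, or adjusted p = 0.556 with an estimated correlation), with the trehalose synthase subunit gene TSL1 at 2.06 and the glycogen synthase gene GSY2 at 1.78. Of 30 seripauperin and cell wall mannoprotein genes of the PAU, DAN and TIR families, 28 rose and 1 fell (median 0.51, adjusted p = 6.15e-07, or adjusted p = 0.556 with an estimated correlation), among them TIR3 at 1.02 and PAU17 at 0.96. Probes of near-identical members may share signal, so counts of these genes, here and in the comparisons below, may not be of separate genes. Of 31 chaperone genes, 22 rose and 3 fell (median 0.77, adjusted p = 0.000185, or adjusted p = 0.571 with an estimated correlation), including HSP82 at 1.77 and HSP104 at 1.70. Thiamine and vitamin B6 genes rose in 14 of 21 cases and fell in 2 (median 0.67, adjusted p = 0.00148, or adjusted p = 0.556 with an estimated correlation). Each of these counts was the same when adjusted over the list alone. No list passed in any comparison with an estimated correlation, a setting that has 2 residual degrees of freedom here and also missed a simulated list shifted by 0.15, 0.25, 0.5, 1 or 2 on the log2 scale. The preset correlation was not tested on simulated lists whose members vary together, so its p-values may be too small.

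**Figure D2:**
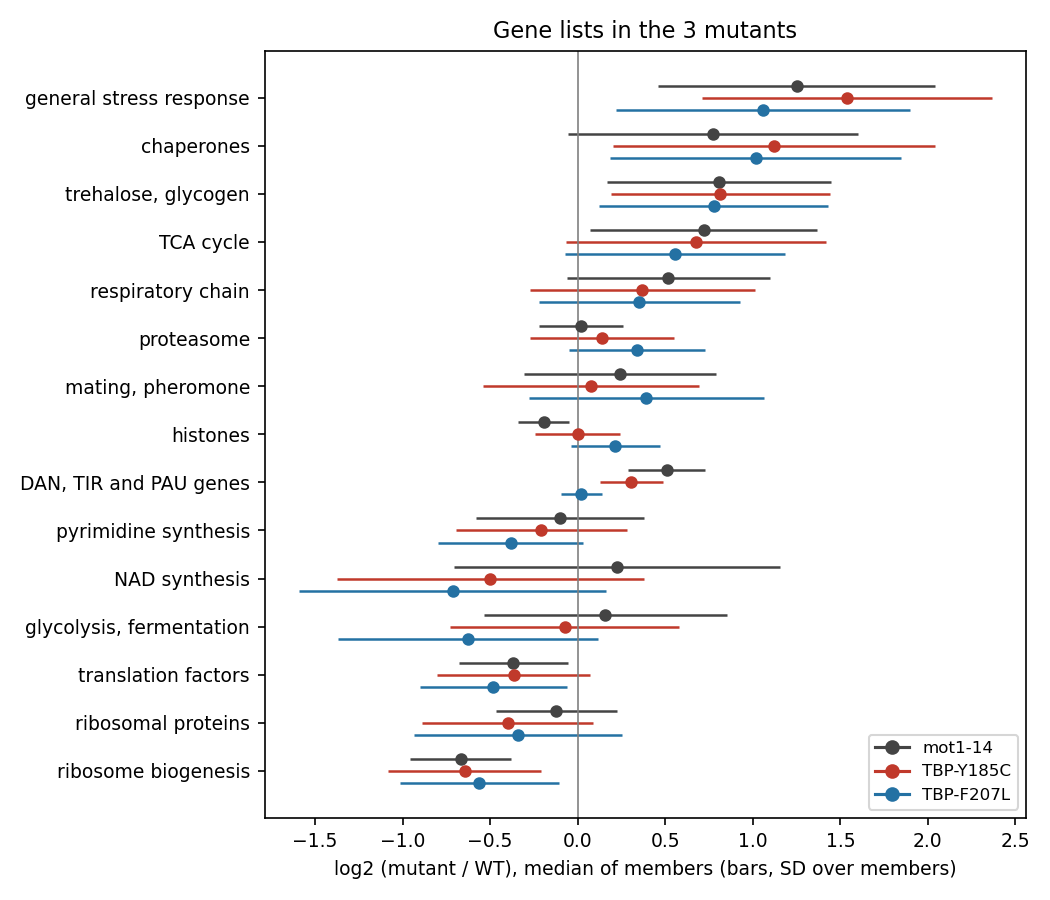
Median log2 ratio of mutant over WT of 15 gene lists in the 3 mutants, with bars for the SD over the members of each list. Ribosome biogenesis lies at -0.67, -0.65 and -0.56 in mot1-14, TBP-Y185C and TBP-F207L and general stress genes at 1.25, 1.54 and 1.06, while glycolysis lies at 0.16, -0.07 and -0.63.

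Genes of the TBP and preinitiation machinery did not differ from the other genes as a list in mot1-14 (12 rose and 22 fell of 45, camera adjusted p = 0.177). Fry, which tests a list against no change, gave an adjusted p of 0.0172. The largest members besides MOT1 were BUR6 and NCB2, the subunits of the negative cofactor that binds TBP, which rose by 1.27 and 0.79. Glycolysis genes divided, with 10 rises and 6 falls among 21 (median 0.16, adjusted p = 0.352). The glucose-repressed hexokinase gene HXK1 rose by 2.14 and the glucokinase gene GLK1 by 1.81. Of 14 NAD synthesis genes, 8 rose and 5 fell (adjusted p = 0.421). BNA4, of the same pathway as BNA1, rose by 1.56 while BNA1 fell, and PNC1, a nicotinamidase, rose by 1.63. These counts too were the same when adjusted over the list alone.

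TBP-Y185C was compared with WT to see how far expression in the bypass strain departs from normal. TMA10 rose 18.9-fold (log2 4.24, SE 0.11, adjusted p = 2.48e-07) and HSP42 12.6-fold (log2 3.65, SE 0.09, adjusted p = 2.39e-07). LEU1, the isopropylmalate isomerase of leucine synthesis, rose by 2.85 (SE 0.03, adjusted p = 5.26e-08), whereas in mot1-14 it was at -0.41. HO was at -1.98 (SE 0.10), BNA1 at -1.73 (SE 0.04) and the ribosomal protein genes RPS8A and RPL20A each at -1.66 (SE 0.05 and 0.04).

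In TBP-Y185C 4972 of 6231 genes passed (79.8%), 2550 higher and 2422 lower, and 522 changed by 2-fold or more, 400 upward and 122 downward. Other large rises were NQM1, a transaldolase homolog, at 3.22, the glucose-repressed alcohol dehydrogenase gene ADH2 at 2.95, STF2 at 2.79, and SER3, which starts serine synthesis, at 2.69. Other large falls were SES1 and YLR126C at -1.72, FDC1 at -1.71, ARX1 at -1.66 and IRC7, a cysteine beta-lyase homolog, at -1.65. The same sign was seen on both arrays for each. INO1 was at 1.41 (adjusted p = 4.41e-07), HSP26 at 2.23 (adjusted p = 2.62e-07) and URA1 at -1.03 (adjusted p = 6.64e-07). Of 15 lists that passed, 12 were higher and 3 lower. General stress genes rose in 42 of 43 cases and fell in 1, 31 of them rising by 2-fold or more (median 1.54, adjusted p = 1.03e-11, or adjusted p = 0.542 with an estimated correlation). Of 31 chaperone genes 28 rose and 1 fell, or 28 and 2 adjusted over the list alone (median 1.12, adjusted p = 1.47e-07, or adjusted p = 0.542 with an estimated correlation). The sorting factor gene BTN2 rose by 2.64 and HSP104, a disaggregase, by 2.34. Ribosome biogenesis genes fell in 76 of 91 cases and rose in 6, or 7 adjusted over the list alone (median -0.65, adjusted p = 1.03e-11, or adjusted p = 0.542 with an estimated correlation). Of 138 ribosomal protein genes 99 fell and 22 rose, the same when adjusted over the list alone (median -0.40, adjusted p = 1.47e-07, or adjusted p = 0.542 with an estimated correlation). Sulfur and methionine genes rose in 21 of 31 cases and fell in 8, also when adjusted over the list alone (median 0.48, adjusted p = 0.0385, or adjusted p = 0.542 with an estimated correlation). MET28, a transcription factor of the pathway, rose by 2.13 and the adenylylsulfate kinase gene MET14 by 2.01. Respiratory chain genes rose in 31 of 43 cases and fell in 3, the same when adjusted over the list alone (median 0.37, adjusted p = 0.000305, or adjusted p = 0.542 with an estimated correlation). Outside these lists, the hexose transporter genes HXT7 and HXT6, near-identical copies that the probes may not separate, were higher by 2.45 and 2.24, and the heme oxygenase gene HMX1 by 2.06. NAD synthesis genes did not pass as a list (4 rose and 10 fell of 15, the same when adjusted over the list alone, median -0.50, adjusted p = 0.0911).

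TBP-F207L was compared with WT in the same way. TMA10 rose 15.5-fold (log2 3.95, SE 0.11, adjusted p = 3.34e-07), HSP42 10.6-fold (log2 3.40, SE 0.09, adjusted p = 2.75e-07) and LEU1 9.47-fold (log2 3.24, SE 0.03, adjusted p = 2.85e-08). The low-affinity glucose transporter genes HXT1 and HXT3 were at -2.36 (SE 0.06, adjusted p = 2.38e-07) and -1.88 (SE 0.03, adjusted p = 1.37e-07), and ENO2, an enolase, and ADH1, the main fermentative alcohol dehydrogenase, were at -1.71 and -1.64.

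In TBP-F207L 4928 of 6232 genes passed (79.1%), 2508 higher and 2420 lower, and 457 changed by 2-fold or more, 310 upward and 147 downward. Other large rises were NCE103, carbonic anhydrase, at 2.74, NQM1 at 2.69, STF2 at 2.60 and CDA1, a chitin deacetylase of the spore wall, at 2.58. Other large falls were RPL20A at -2.08, the multidrug transporter gene AQR1 at -1.85, YAR075W at -1.84, BNA1 at -1.79, HXT4 at -1.75, the IMP dehydrogenase gene IMD2 at -1.74 and INA1 at -1.74. YAR075W and IMD2 belong to a family of near-identical sequences, so their values are uncertain. The sign was the same on both arrays for each. INO1 was at 0.93 (adjusted p = 2.53e-06), HSP26 at 0.86 (adjusted p = 1.29e-05) and URA1 at -0.94 (adjusted p = 1.07e-06). Of 18 lists that passed, 11 were higher and 7 lower. Glycolysis and fermentation genes fell in 16 of 21 cases and rose in 4 (median -0.63, adjusted p = 0.00884, or adjusted p = 0.545 with an estimated correlation), including the pyruvate kinase gene CDC19 at -1.37 and the phosphofructokinase gene PFK1 at -1.20. NAD synthesis genes fell in 12 of 15 cases and rose in 3 (median -0.71, adjusted p = 0.0195, or adjusted p = 0.545 with an estimated correlation), with BNA5 at -1.42 and the nicotinic acid transporter gene TNA1 at -1.19, while PNC1 rose by 1.68. Proteasome genes rose in 24 of 33 cases and fell in 4 (median 0.34, adjusted p = 0.000612, or adjusted p = 0.545 with an estimated correlation). RPN4, the transcription factor of the proteasome genes, rose by 1.44 and the subunit gene PRE6 by 1.17. Mating genes rose in 25 of 39 cases and fell in 10 (median 0.39, adjusted p = 0.0266, or adjusted p = 0.674 with an estimated correlation), among them the pheromone-induced genes FIG1 at 1.55, PRM5 at 1.47 and PRM2 at 1.41. These 4 counts were the same when adjusted over the list alone. General stress genes rose in 39 of 43 cases and fell in 1, or 2 adjusted over the list alone (median 1.06, adjusted p = 6.08e-10, or adjusted p = 0.545 with an estimated correlation). Chaperone genes rose in 28 of 31 cases and fell in 3 (median 1.02, adjusted p = 2.93e-07, or adjusted p = 0.545 with an estimated correlation), and ribosome biogenesis genes fell in 76 of 91 cases and rose in 9 (median -0.56, adjusted p = 2.74e-10, or adjusted p = 0.545 with an estimated correlation), both the same when adjusted over the list alone. Ribosomal protein genes fell in 87 of 139 cases, or 88 adjusted over the list alone, and rose in 31 (median -0.34, adjusted p = 0.000272, or adjusted p = 0.545 with an estimated correlation). PAU, DAN and TIR genes, which had risen in mot1-14, did not pass as a list (9 rose, 4 fell and 17 did not pass, or 6 and 4 adjusted over the list alone, median 0.02, adjusted p = 0.876), and their median took the other sign, at -0.0093, with the deposited log ratios. Hexose transport genes did not pass as a list either (7 rose and 11 fell of 25, the same when adjusted over the list alone, adjusted p = 0.664), and HXT7 rose by 1.66. On the first TBP-F207L array the red channel, which held the mutant RNA, had a higher floor than elsewhere. The median of its negative control spots was 55.7, against 37.6 to 40.5 on the other arrays, and the 1st percentile of gene spots 135.5, against 43.0 to 54.4, while the red signal of MOT1 there was 622. The green channel of that array, with WT RNA, was raised too. Its negative control spots had a median of 46.5, against 37.8 to 41.8 elsewhere, and its 1st percentile was 73.9, against 43.0 to 51.2.

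The next comparison asked which of the genes changed in mot1-14 were at WT levels in the strains where a TBP variant replaced Mot1. The bypass strains differ from mot1-14 in Mot1 as well as in TBP, with MOT1 transcript raised in mot1-14 and low in them. The classes below therefore cannot tell an effect of the TBP variant from that of a mot1 allele against loss of Mot1. COS8, of a subtelomeric membrane protein family, had risen by 1.68 in mot1-14 and was at 0.17 in TBP-Y185C (adjusted p = 0.0856) and -0.15 in TBP-F207L (adjusted p = 0.114), with both differences from mot1-14 passing (adjusted p = 0.000167 and 4.88e-05). SHR5, a palmitoyltransferase subunit, had risen by 1.68 and was at -0.03 in TBP-F207L (adjusted p = 0.469) but still raised in TBP-Y185C at 0.66. TMA10, HSP42, CYC7, BNA1, TMA20 and DBP2 kept their mot1-14 change in both strains. BNA4 and OAC1 had passed to the other side of WT in both.

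In TBP-Y185C, 340 of the 4464 mot1-14 genes measured there were restored (7.62%), 464 were partly restored (10.4%), 3138 were retained (70.3%), 282 were changed in the opposite direction (6.32%) and 240 were unresolved. In TBP-F207L, 480 of 4465 were restored (10.8%), 654 partly restored (14.6%), 2651 retained (59.4%), 489 opposite in direction (11%) and 191 unresolved. Of the retained genes, 1323 in TBP-Y185C and 1142 in TBP-F207L were changed by significantly more than in mot1-14. With no dye term 160 genes were restored in TBP-Y185C. Simulated mutants without any effect, but with variation between extracts, had on average 857 and 864 restored genes in the 2 strains, more than observed. The size of the restored class alone therefore does not show restoration beyond such variation. Both strains shared 125 restored genes (36.6 if the lists were independent) and 2417 retained genes (1864 if independent). Both lists use the same mot1-14 arrays and the same WT, and simulated mutants without any effect, measured against 1 shared WT extract, shared 243 restored genes (177 if independent) and 1054 retained genes (822 if independent). The retained overlap was thus 1.30 times its independent value against 1.28 times in the simulation, and the restored overlap 3.42 times against 1.37 times. Such ratios depend on the sizes of the lists, and the simulated lists held on average 1858 and 1854 retained and 857 and 864 restored genes. The observed and simulated ratios therefore cannot be set against each other, and part of the overlaps may come from the shared arrays. Among the 312 genes changed 2-fold in mot1-14, 5 were restored, 92 partly restored, 212 retained and 3 opposite in TBP-Y185C, and 7, 147, 150 and 8 in TBP-F207L. Of the 276 genes that had risen 2-fold in mot1-14, the median share of the log2 rise left was 101% in TBP-Y185C and 78.2% in TBP-F207L, and 31 and 59 genes had under 50% left. Between the single arrays of the strain, this median had an SD of 0.041 percentage points in TBP-Y185C and 10.4 in TBP-F207L. The first TBP-F207L array had the raised floor described above, and its effect on the share was not tested. Genes picked on 1 mot1-14 array and measured on the other gave medians of 103% and 104% for TBP-Y185C and 79.2% and 80.6% for TBP-F207L. For the 36 genes that had fallen 2-fold the share left was 112% and 101%.

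The largest restored rises in TBP-Y185C were YIR043C (2.07 in mot1-14, -0.06 in TBP-Y185C), COS8, the acid phosphatase gene PHO12 (1.18 and 0.17), COS1 (1.17 and -0.04) and YIR016W (1.15 and 0.09). COS genes and PHO12 have near-identical copies, so their values are uncertain. The largest restored falls were FET3, the oxidase of iron uptake (-0.82 and -0.06), CRP1 (-0.63 and 0.08), the hexose transporter gene HXT2 (-0.59 and 0.03), and the ribosome assembly genes RPF1 (-0.58 and -0.07) and RRP14 (-0.58 and 0.01). In TBP-F207L the restored rises also held DFP4 (1.46 and 0.04), NRE1 (1.27 and -0.06) and the polyamine oxidase gene FMS1 (1.11 and -0.11). The restored falls held the leucyl-tRNA synthetase gene CDC60 (-0.89 and -0.06), the chorismate synthase gene ARO2 (-0.75 and -0.08), CRP1, ENB1 (-0.56 and -0.03) and MCH4 (-0.55 and -0.01). Retained rises were led by TMA10, HSP42 and CYC7, at 2.59 in TBP-Y185C and 2.27 in TBP-F207L, and by AIM19 and HSP30 in the first strain and NQM1 and STF2 in the second. Retained falls included TMA20, at -1.51 in TBP-Y185C and -1.46 in TBP-F207L, and DBP2, at -1.62 and -1.58. Of genes that changed sides, BNA4 went from 1.56 in mot1-14 to -0.50 in TBP-Y185C and -0.98 in TBP-F207L, and the methylglyoxalase gene HSP31 from 0.97 to -0.43 and -0.82. The metalloreductase gene FRE7 went from 0.87 to -0.92 and -0.97. In the other direction OAC1, the mitochondrial oxaloacetate carrier gene, went from -0.84 to 2.14 and 2.46, DRE2, of iron-sulfur cluster assembly, from -0.84 to 0.80 and 0.76, and the aldehyde dehydrogenase gene ALD5 from -0.64 to 0.73 and 0.67.

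**Figure D3:**
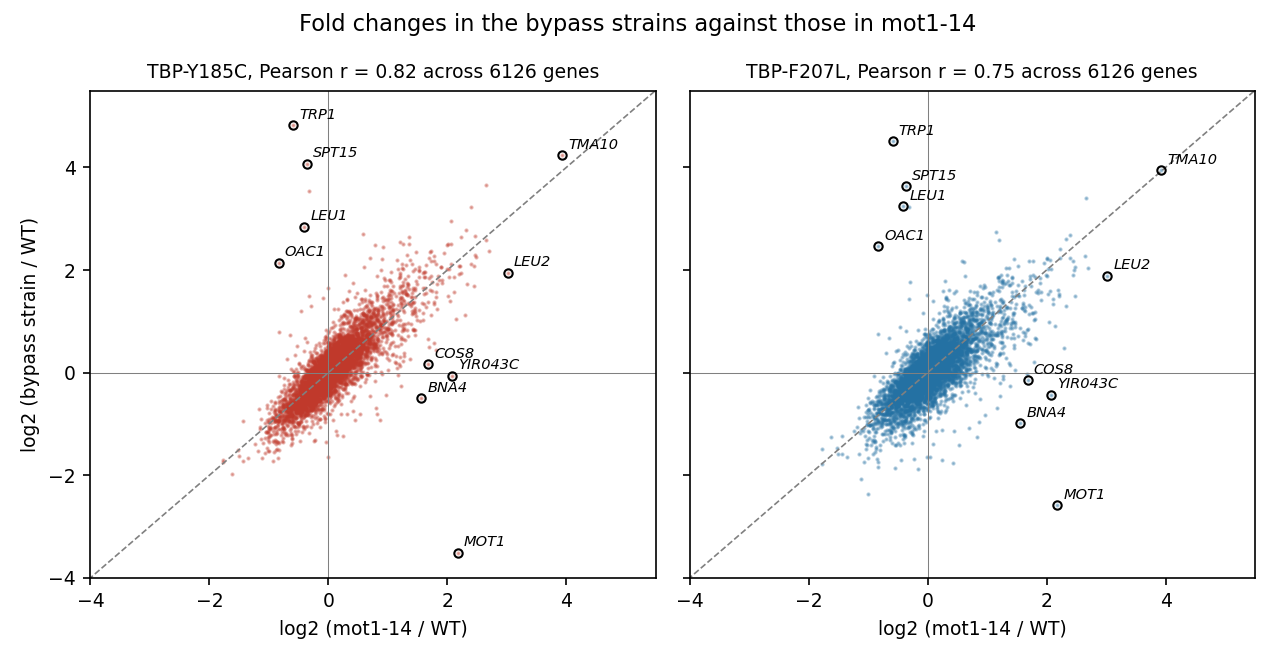
Log2 ratio of each bypass strain over WT against that of mot1-14 over WT, 1 point per gene, with selected genes circled and named and a dashed line where both ratios are equal. Pearson r across 6126 genes is 0.82 for TBP-Y185C and 0.75 for TBP-F207L, and MOT1, SPT15, TRP1, LEU1 and OAC1 lie away from the diagonal.

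The study also asked which genes departed from WT in a bypass strain and not in mot1-14. Newly misregulated genes passed against WT in a bypass strain, did not pass in mot1-14 and differed from mot1-14 by the test of the difference. There were 621 in TBP-Y185C (311 higher, 310 lower) and 788 in TBP-F207L (393 higher, 395 lower), but 5 and 9 of them changed by 2-fold or more. Simulated mutants without any effect, but with variation between extracts, had on average 917 and 922 such genes, more than observed. The size of this class alone therefore does not show changes beyond such variation. Both strains shared 479, of which 464 moved the same way (294 shared if the lists were independent). Both lists use the same mot1-14 arrays and WT, and the simulated mutants without any effect shared 462 (436 if independent). That was 1.06 times against 1.63 times observed, but the lists differ in size, so these ratios cannot be set against each other. Part of the overlap may come from the shared arrays. ISU2, a scaffold of iron-sulfur cluster assembly, rose by 1.65 in TBP-Y185C and 1.52 in TBP-F207L and was at -0.01 in mot1-14. CLD1, a cardiolipin lipase, rose by 1.45 and 1.17 (-0.08 in mot1-14), and IRC7 was at -1.65 in both (-0.01 in mot1-14). In TBP-Y185C the next rises were DAL80, a repressor of nitrogen genes, at least 2.14-fold, YGL138C at least 1.96-fold and REX3 at 0.92. For DAL80 and YGL138C the WT signal was not well above background on these arrays, and the bound is taken against the lowest measured signal. The next falls there were YLR162W at -1.35, RNH203 at -0.98, the serine deaminase gene CHA1 at -0.95 and the aquaporin gene AQY2 at -0.92. In TBP-F207L the next rises were HOM2, of threonine and methionine synthesis, at 1.04, the RNA polymerase subunit gene RPC37 at 0.86 and the SAGA subunit gene SPT20 at 0.85, and the next falls ADH1 at -1.64, AQY2 at -1.39, GRE2 at -1.23 and EHT1 at -1.13. Without the first TBP-Y185C array 307 genes were newly misregulated in that strain, and with no dye term 273 there and 478 in TBP-F207L. A count chosen after the data were seen took genes at least 2-fold from both WT and mot1-14 in the same direction, whether or not they passed in mot1-14. It found 41 genes in TBP-Y185C and 46 in TBP-F207L, of which 37 and 39 passed in mot1-14.

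The fold changes of the 3 mutants were correlated with each other across 6126 genes, which are not independent replicates. Pearson r was 0.82 between mot1-14 and TBP-Y185C (Spearman rho 0.82), 0.75 between mot1-14 and TBP-F207L (rho 0.73) and 0.93 between the bypass strains (rho 0.90). Simulated mutants without any effect, measured against 1 shared WT extract, gave r of 0.48 in each case. That value follows from giving every extract the same SD. It does not measure how much of the observed r came from the shared WT, though part of it may. The observed covariances were 0.233, 0.197 and 0.30 and the simulated ones 0.0231, 0.0230 and 0.0228. The covariance of the bypass strains exceeded that of mot1-14 and TBP-Y185C by 0.0668, or by 0.0360 to 0.0988 over 8 choices of single arrays. Genes changed 2-fold the same way in mot1-14 and TBP-Y185C numbered 234 (18.6 if independent), of which 27 were lower (0.705 if independent). For mot1-14 and TBP-F207L, 160 genes were higher in both (13.8) and 27 lower (0.858), and for the bypass strains 271 were higher (19.9) and 83 lower (2.88). The simulated mutants shared 0 such genes in each pair, and part of these overlaps may also come from the shared WT. In all 3 mutants 157 genes rose and 25 fell by 2-fold or more.

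The bypass strains were then compared directly with mot1-14. Besides TRP1, SPT15 and PEA2, the genes most raised over mot1-14 were LEU1 (by 3.25 in TBP-Y185C, SE 0.05, adjusted p = 2.49e-07, and by 3.65 in TBP-F207L, SE 0.05, adjusted p = 1.51e-07) and OAC1 (by 2.98 and 3.30). MOT1 was lower by log2 differences of -5.68 and -4.75. YIR043C followed at -2.13 and -2.50, BNA4 at -2.06 and -2.54, FRE7 at -1.79 and IRC7 at -1.64 in TBP-Y185C, and HXT4 at -2.17 and the cell wall protein gene CWP1 at -2.07 in TBP-F207L. In total 3044 of 6126 genes differed between TBP-Y185C and mot1-14 (1564 higher, 1480 lower), 73 by 2-fold or more, and 3565 of 6127 between TBP-F207L and mot1-14 (1750 higher, 1815 lower), 92 by 2-fold or more. Proteasome genes were higher than in mot1-14 in 23 of 33 cases in TBP-Y185C and lower in 2 (median 0.24, adjusted p = 5.16e-06, or adjusted p = 0.600 with an estimated correlation). In TBP-F207L they were higher in 29 and lower in none (median 0.40, adjusted p = 2.05e-09, or adjusted p = 0.607 with an estimated correlation). PAU, DAN and TIR genes were lower in 14 of 30 cases and higher in 1 in TBP-Y185C (median -0.15, adjusted p = 0.00285, or adjusted p = 0.600 with an estimated correlation), and lower in 28 and higher in none in TBP-F207L (median -0.48, adjusted p = 6.07e-09, or adjusted p = 0.607 with an estimated correlation). Glycolysis genes were lower in 14 of 21 cases and higher in 3 in TBP-Y185C (median -0.35, adjusted p = 0.0172, or adjusted p = 0.600 with an estimated correlation), and lower in 18 and higher in none in TBP-F207L (median -0.78, adjusted p = 2.19e-07, or adjusted p = 0.607 with an estimated correlation). Histone genes were higher than in mot1-14 in 9 of 10 cases in TBP-F207L (median 0.39, adjusted p = 0.00205, or adjusted p = 0.607 with an estimated correlation). These counts were the same when adjusted over the list alone. Each pair of arrays lay on a slide of its own, so slide and mutant cannot be told apart in direct comparisons. Without the first TBP-Y185C array 1571 genes differed between TBP-Y185C and mot1-14, without the second 1993 and without the second mot1-14 array 1890, and a fit with no dye term called 963 there and 1572 for TBP-F207L.

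The bypass strains differed less from each other. The a-factor gene MFA1 was higher in TBP-F207L (log2 1.30, SE 0.08, adjusted p = 0.00042), as were ASG7 (1.29, SE 0.05, adjusted p = 0.00026) and FIG1 (1.16, SE 0.15, adjusted p = 0.0023). HSP26 was lower in TBP-F207L (-1.38, SE 0.08, adjusted p = 0.000447), as were HXT1 (-1.20), NCA3 (-1.13), GID10 (-1.06) and ADH1 (-1.04, SE 0.26, adjusted p = 0.0237). In total 2311 of 6231 genes differed (952 higher in TBP-F207L, 1359 lower), 13 of them by 2-fold or more. Mating genes were higher in 25 of 39 cases and lower in 2, or 26 and 3 adjusted over the list alone (median 0.29, adjusted p = 3.76e-08, or adjusted p = 0.491 with an estimated correlation). Glycolysis genes were lower in 15 of 21 cases and higher in none, the same when adjusted over the list alone (median -0.47, adjusted p = 3.76e-08, or adjusted p = 0.451 with an estimated correlation). PAU, DAN and TIR genes were lower in 26 of 30 cases, or 29 adjusted over the list alone (median -0.29, adjusted p = 9.11e-09, or adjusted p = 0.451 with an estimated correlation). General stress genes were lower in 26 of 43 cases and higher in 2, or 28 and 2 adjusted over the list alone (median -0.30, adjusted p = 2.33e-05, or adjusted p = 0.503 with an estimated correlation). Genes of the TBP and preinitiation machinery were higher in 19 of 45 cases and lower in 3, or 23 and 3 adjusted over the list alone (median 0.17, adjusted p = 3.95e-05, or adjusted p = 0.451 with an estimated correlation). This count of differing genes was the least stable, at 640 without the first TBP-Y185C array, 924 without the second, 1321 with median centring, 1408 with the deposited log ratios and 118 with no dye term, and with no dye term the share of higher calls moved by -15.8 percentage points.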

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

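The tests of the LEU2 transcript level, and of chromosome ends in TBP-Y185C, were chosen only after the result was seen; the other tests in this part were set beforehand. For position near a chromosome end the rule was changed after the result was seen, to need genes outside the families, which turned its verdict from supported to open. A further 3 comparisons made after the result was seen are given in the report as values: the red signal of MOT1 on the first TBP-F207L array, which was 4.59 times the 1st percentile there, the smallest covariance between mutants, and the excess covariance of the bypass strains. The first and the last spoke against a raised floor and against WT RNA that deviates alike on all arrays as whole explanations, and the second decided nothing.

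Genes that passed against WT in opposite directions in mot1-14 and a bypass strain, with the difference itself passing limma's test, numbered 282 for TBP-Y185C and 489 for TBP-F207L. Among these genes, differences from mot1-14 of at least 2 on the log2 scale in TBP-Y185C were MOT1 (-5.68), TRP1 (5.42), SPT15 (4.44), PEA2 (3.86), LEU1 (3.25), OAC1 (2.98) and BNA4 (-2.06). In TBP-F207L they were TRP1 (5.10), MOT1 (-4.75), SPT15 (3.99), LEU1 (3.65), PEA2 (3.55), OAC1 (3.30), BNA4 (-2.54), YIR043C (-2.50), HXT4 (-2.17), CWP1 (-2.07) and the acetolactate synthase gene ILV2 (2.06). Of these genes MOT1, TRP1, SPT15 and PEA2 may reflect the strain construction. The median of NAD synthesis genes against WT lay -0.72 from that in mot1-14 in TBP-Y185C, while the median of the direct differences was -0.30 (adjusted p = 0.0158, or adjusted p = 0.600 with an estimated correlation). In TBP-F207L the 2 values were -0.94 and -0.43 (adjusted p = 0.00169, or adjusted p = 0.607 with an estimated correlation). For glycolysis genes in TBP-F207L both were -0.78 (adjusted p = 2.19e-07, or adjusted p = 0.607 with an estimated correlation), and for histone genes there 0.41 and 0.39 (adjusted p = 0.00205, or adjusted p = 0.607 with an estimated correlation). The histone gene HHT1 among them, at 0.27 in TBP-F207L, was at -0.042 with median centring. Outside the gene probes, negative control spots on the first TBP-F207L array had a median red signal of 55.7, above the 37.6 to 40.5 of the other arrays. Their median green signal was raised too, at 46.5 against 37.8 to 41.8.

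MOT1 fell less on the first TBP-F207L array (-1.74) than on the second (-3.41). WT RNA in the mutant channel would have to make up 25% of it to give that MOT1 value, and would then compress the 119 genes that fell 2-fold in TBP-Y185C by a median of 0.39, but the median compression was 0.0956 (quartiles 0.04 and 0.18), which argues against it. The single MOT1 spot was no more uneven than many others, its pixel spread lying at percentile 84.8 of 3481 spots of like signal. The 13 neighbouring spots differed by a median of -0.035 (-0.21 to 0.14), so red signal spread over that area was not seen. The difference stays open, no biological explanation was tested, and MOT1 stood at -3.49 without the first array and -1.66 without the second.

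Target genes of Leu3, the activator of leucine and branched-chain amino acid genes, were higher than WT in both bypass strains, while in mot1-14 2 of 7 were higher and 5 lower. The 7 targets, listed from background knowledge after LEU1 had been seen, had a median of -0.29 in mot1-14, 1.49 in TBP-Y185C and 1.77 in TBP-F207L, and all 7 exceeded mot1-14 in both strains by limma's test. If LEU2 transcript set their level, their median would follow it. LEU2 was highest in mot1-14 (3.02), where the targets' median was -0.29, so the median did not follow the LEU2 transcript across the mutants. This prediction was written after these values had been seen, so its outcome was fixed and it is no independent test. An effect of LEU2 as a marker, other than through its transcript level, was not tested. A raised level of TBP in place of the amino acid change cannot be told apart, since SPT15 was raised by at least 3.63 in both bypass strains and no strain held wild-type TBP at that level. The bypass strains also had less MOT1 transcript than mot1-14, which was not separated from the variants either. A direct effect of the TBP variants therefore remains an untested hypothesis.

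Genes that had risen 2-fold in mot1-14 and kept under 50% of the rise in TBP-F207L lay near chromosome ends more often than the other rises. Within 15 genes of an end lay 13 of 56 (23.2%) against 24 of 214 (11.2%), an odds ratio of 2.38 (Fisher's exact test, two-sided, p = 0.0282), which restates the pattern and is no separate evidence for position. For TBP-Y185C the counts were 13 of 30 (43.3%) and 24 of 240 (10.0%), an odds ratio of 6.80 (Fisher's exact test, p = 1.81e-05). Genes named as COS, PAU, DAN, TIR or Y' genes were then left out, while any family member under a systematic name stayed in. The odds ratio in TBP-F207L was then 1.32 (95% interval 0.449 to 3.43, 7 of 49 against 24 of 214, Fisher's exact test, p = 0.623). Near-identical families at the ends, which would count several times if their members shared probe signal, could give such a fall. All genes left out came from the group with under 50% left, most of them near an end. The fall was thus built in and is no evidence for families. In TBP-Y185C the odds ratio was 3.91 (95% interval 1.23 to 11.3, 7 of 23 against 24 of 240, Fisher's exact test, p = 0.0101). Families thus remain a possible explanation in TBP-F207L, position outside them was not resolved there, shared signal was not tested, and the p-values treat family members as independent.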

How the results depend on the processing

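The counts of genes by 2-fold sizes alone, set beside the restored and newly misregulated classes, were chosen only after the data were seen; the other alternatives were set beforehand. No paired analysis was possible because the replicate numbers were given in the order of deposit and stand for the dye orientation, which the model already holds as its dye term, and each array holds its own WT. Of 306 values for the main results under alternatives 263 were unchanged, 42 moved and 1 lost its call, where a count moved if it went beyond 1.5 times, and a share left or a correlation if it moved by more than the SD between single arrays, and for named genes 9384 of 9491 values were unchanged in direction and call, 47 lost it, 59 gained it and 1 reversed: HHT1 in TBP-F207L, at -0.042 with median centring (adjusted p = 0.645). Among lists that passed, 3 had a median of the other sign under a different scaling, each with median centring: ribosomal protein genes (-0.10) and ribosome biogenesis genes (-0.010) between the bypass strains and meiosis genes (-0.067) in TBP-Y185C against mot1-14. The causes of these shifts were not tested, except that a stricter threshold by its construction calls fewer genes. Some values counted as unchanged could not move. The correlation of mot1-14 and TBP-Y185C, for example, takes nothing from the TBP-F207L arrays, so leaving either out cannot shift it. The numbers unchanged therefore overstate stability.

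With a 2-fold threshold 312 genes passed in mot1-14, 522 in TBP-Y185C and 457 in TBP-F207L, 73 and 92 in the comparisons of the bypass strains with mot1-14, and 13 between them; restored genes were then 28 and 56 and newly misregulated genes 264 and 245, of which only 5 and 7 and 5 and 9 were in the classes of the report, since genes that passed in a strain below 2-fold then counted as unchanged there. The deposited p-values on both arrays gave 1512, 2066 and 1399 genes for the 3 mutants. With no dye term, 963 and 1572 genes differed between TBP-Y185C or TBP-F207L and mot1-14 and 118 between the bypass strains, with 160 restored genes in TBP-Y185C and 273 and 478 newly misregulated genes. Class counts that stayed within 1.5 times could still hold other genes: with median centring 145 of 340 and 261 of 480 restored genes and 314 of 621 and 499 of 788 newly misregulated genes were in the class again, and without the second mot1-14 array 320 and 490 of the newly misregulated genes. The bypass strains differed in 1408 genes with the deposited log ratios, 1321 with median centring and 1457 with the series table. The counts added later drop a condition of the classes: 31 and 59 genes changed 2-fold in mot1-14 had under 50% of the change left, whether or not they still passed against WT, and 41 and 46 genes lay 2-fold from WT and mot1-14, whether or not they passed in mot1-14. The share of the mot1-14 rise left in TBP-Y185C was 103% and 104%, and that of the fall left in TBP-F207L 113% and 97.8%, with genes picked on 1 array and measured on the other. Estimated correlation left 0 of 41 lists in each mutant (2, 0 and 0 at an unadjusted p under 0.05), and fry called 34, 35 and 38.

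Leaving out 1 array at a time gave 1571 to 3589 genes for TBP-Y185C against mot1-14 (1571 and 1993 without the first and second TBP-Y185C array, 1890 without the second mot1-14 array) and 640 to 2417 between the bypass strains (640 and 924 without the first and second TBP-Y185C array). Newly misregulated genes in TBP-Y185C ranged from 307, without its first array, to 713, and SPT15 in mot1-14 from -0.60 to -0.12, the latter without the first mot1-14 array and not passing. The array left alone was assumed to vary like the others. Signal limits dim genes: up to 69 genes had a WT signal not well above background on both arrays of a mutant.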

Other observations

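The gene families and single genes in this part were chosen only after their values were seen, except for members of the lists fixed beforehand, and each value is from the limma model. The Leu3 target genes moved in the bypass strains by unequal amounts: LEU1 by 2.85 in TBP-Y185C and 3.24 in TBP-F207L, OAC1 by 2.14 and 2.46, LEU4, which starts leucine synthesis, by 1.91 and 1.79, the aminotransferase gene BAT1 by 1.49 and 1.44, ILV2 by 1.30 and 1.77, the glutamate dehydrogenase gene GDH1 by 1.17 and 1.18, and ILV5 by 0.34 and 0.23. In mot1-14, 2 of the 7 were higher than WT, LEU4 at 0.29 and GDH1 at 0.34, and 5 were lower. Of 12 COS genes, whose probes may share signal, 11 were higher than WT in mot1-14 (median 1.02). In TBP-Y185C 5 were higher and 2 lower (median 0.06), and in TBP-F207L 2 were higher and 8 lower (median -0.16). The difference from mot1-14 passed downward for 10 of them in TBP-Y185C and 11 in TBP-F207L.

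Genes of NAD synthesis from tryptophan went different ways in mot1-14. BNA1 fell in all 3 mutants, at -1.77, -1.73 and -1.79 in mot1-14, TBP-Y185C and TBP-F207L. BNA4 and BNA5 rose in mot1-14, by 1.56 and 0.53, and were at -0.50 and -0.80 in TBP-Y185C and -0.98 and -1.42 in TBP-F207L. BNA7 was at 0.15, -1.22 and -1.13. The metallothionein gene CUP1-1, which has a near-identical copy, rose in all 3, the largest rise being 2.49 in TBP-Y185C. In both bypass strains 23 genes were at least 2-fold from both WT and mot1-14, 18 higher and 5 lower, and 20 of the 23 had passed in mot1-14 too. Among the 23 were MOT1, SPT15, PEA2 and TRP1, which may reflect the strain construction.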
